A study of Mus musculus with 8 samples.

How the data were processed

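Cardiac RNA from C57BL/6J mice with a ligated left anterior descending coronary artery was sequenced in 8 libraries, 4 labelled vehicle and 4 labelled DAPA. Per the labels' protocols, RNA was taken up in TRIzol, libraries were made with a stranded mRNA kit (TruSeq) that keeps the strand of each transcript, paired reads of 150 bases were produced on an Illumina instrument, and reads were trimmed with Trimmomatic. Per the submitters' processing notes, the tools were HISAT2, SAMtools, StringTie, Cufflinks, HTSeq and DESeq, listed without versions or roles. The genome build in the same notes is GRCh38, a human assembly, while the symbols and NCBI Gene identifiers in the table are those of mouse genes. Because the build behind the values is therefore unclear, no coordinates are given. Of the 22173 identifiers, 21979 (99.1%) matched the RefSeq annotation of the mouse assembly GRCm38.p6, which was used for names only, and 98.8% of those are protein-coding. None was a mitochondrially encoded gene. Whether HTSeq counted by strand is not given in the sources used here, so overlapping and antisense gene pairs, and families of near-identical genes such as Ifit3 and Ifit3b, carry uncertain values.

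The expression values are FPKM (fragments per kilobase of transcript, scaled to the total mapped in the library), computed by the authors for each library, with no library pooled. The deposited table also carries the authors' own comparison, a ratio of DAPA over vehicle (fold change) and a q-value computed by the authors. That ratio is given for 15527 genes and left empty for 6646. No per-sample column was left without a sample.

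FPKM values are not counts. Within each gene they were whole multiples of a fixed step in all 8 libraries, so that the reads behind them came back as whole numbers for 17355 of the 17356 genes with a value above 0 (100.0% of the values above 0, tolerance 0.0001 reads). The exception was Kcnip4, singled out after its values were seen, with at most 0.0042 FPKM in any library. On simulated reads for 17355 genes, 98.59% of genes came back exactly, and 99.82% of those with at least 100 reads. The totals by which the authors divided ranged from 24990393 to 26823456 reads, or read pairs, per library. The genes of the table hold 99.91% to 99.92% of them. For a transcript of 1 kilobase, 1 read is worth 0.0373 to 0.04 FPKM. Recovered reads served to state depth, to compare libraries with sampling noise and for 1 added alternative. Intervals on ratios of reads are exact binomial (Clopper-Pearson) at 95%, and cover counting error only.

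The design fixed before the data were examined assumed counts and named a count model as the main test, with a stated fallback for FPKM. The fallback was used, because the deposited unit is FPKM: limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), with genes of mean FPKM 1 or more in at least 1 group, all 8 libraries and group as the only term. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over 11496 genes. All adjusted p-values of single genes come from this limma fit unless another is named. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values, so ratios of mean FPKM are given beside them, and list medians printed on that scale understate lists with low members, such as the adipocyte markers. The fit was tested on simulated reads for this comparison with 11446 genes, of which 50 were changed at each of 4 sizes. It recovered 26% of genes changed 1.2-fold, 94% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, and 6 of its 166 calls (3.6%) were false. The minimum-fold test recovered 21 of 50 genes changed 2-fold and 44 of 50 changed 4-fold.

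A set of 62 gene lists (pathways, cell type markers and signs of RNA quality), also fixed before the data were examined, was tested with camera in limma at a preset correlation of 0.01 between genes, for the 55 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over those lists. The preset test was repeated with a correlation estimated for each list, and that p is printed beside each call that it ends. That setting also takes its degrees of freedom from the 8 libraries instead of the genes, so it is stricter even at an equal correlation. In the simulation, whose genes were independent, none of the 55 lists was called when none was changed. Mean log2(FPKM + 1) over the markers of each cell type or quality list was compared per library with an exact two-sided permutation test over all 70 assignments of 8 libraries to 4 and 4, adjusted over 25 lists. Total reads and the number of genes above 0 were compared in the same way.

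Genes were named by a rule fixed before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean FPKM of 1 or more and no overlap between groups, leaving out predicted genes and pseudogenes. To these it added up to 4 members with the smallest p of each list described, a fixed set of 15 genes tied to the drug and to infarction, and the 5 genes with the smallest p. The rule was written for CPM and was applied to FPKM. A few genes that the rule takes, or that a count would name, are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

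Nothing in the labels says that the 4 libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical. Replicates were compared with sampling noise before they were averaged. Over genes with more than 40 reads in a pair of libraries, the chi-square per degree of freedom was 3.61 to 8.19 within groups (12 pairs) and 19.1 to 23.3 between groups (16 pairs). No pair agreed within sampling noise, and all 8 libraries were kept.

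The alternatives covered median-of-ratios and upper-quartile scaling, no filter and a stricter filter, pseudocounts of 0.1 and 0.01, sample quality weights, robust moderation of the variance, the replicate number as a block, each library left out, other thresholds, a minimum fold of 1.5 (limma treat), and for the lists an estimated correlation and the rotation test fry. Chosen after seeing the data were limma voom on the recovered reads and a count that leaves out the lists of atrial, conduction, epicardial, Schwann cell and adipocyte markers. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.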

Results

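Heart tissue of C57BL/6J mice was profiled by mRNA sequencing after ligation of the left anterior descending coronary artery, the operation that infarcts the wall of the left ventricle. DAPA, the usual short form of dapagliflozin, blocks SGLT2, the cotransporter by which the kidney takes glucose back from urine. 4 libraries came from mice given vehicle and 4 from mice given DAPA at 1 mg/kg per day for 4 weeks after surgery. The libraries were of like depth. The reads behind the FPKM values came to 26038038 ± 780285 per vehicle library and 26032062 ± 569337 per DAPA library (mean ± SD, n = 4 each; exact two-sided permutation p = 0.943). Between 15687 and 15799 genes had a value above 0. That number was higher in each DAPA library, 15778 ± 22 against 15706 ± 20, at the smallest p that 70 assignments allow (exact permutation p = 0.0286). The 10 most abundant genes took 9.64% to 10.14% of the reads in each library. On the first principal component, which carried 64.8% of the variance, the vehicle libraries lay between -13.43 and -12.45 and the DAPA libraries between 12.62 and 13.28. All values below are FPKM, given as mean ± SD over the 4 libraries of a group.

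The comparison asked which transcripts differ in infarcted hearts when the SGLT2 inhibitor is given. Genes of the atrial myocardium showed the largest rises with DAPA. Genes of adipocytes and the circadian clock, and the plasma cell gene Jchain, were among the largest falls. Interferon-stimulated genes fell nearly throughout, and most genes of the unfolded protein response rose. Of 11496 genes tested, 1106 were higher and 1006 lower with DAPA (limma-trend, Benjamini-Hochberg adjusted p below 0.05). The typical change was small, with a median size of 0.25 on the log2 scale among the 2112 genes called, and 41 called genes rose and 27 fell by at least 1 on that scale. Against a minimum fold of 1.5, 81 genes passed, 43 higher and 38 lower. In 2536 genes (22.1%) the 4 DAPA libraries did not overlap the 4 vehicle libraries, where chance gives 2.86%. In the simulation, with 4 libraries a group, 26% of genes changed 1.2-fold were recovered, so small changes can be missed. Few genes were changed there, and 166 were called against 2112 here. The adjusted threshold loosens as more genes are called, so 26% is not the rate of recovery in this comparison.

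The authors' deposited table lists 206 genes higher and 131 lower at q below 0.05 and a fold above 2. Of these, 71 and 66 also reached a mean FPKM of 1 in a group, and 71 and 65 of those were called in the same direction here. At a fold above 1.5, the authors' deposited table holds 357 higher and 293 lower genes. Of that table's genes, 177 and 190 were tested here, and 177 and 185 were called in the same direction. With q below 0.05 at any fold, the authors' deposited table holds 1360 higher and 1343 lower genes, of which 1162 and 1226 were tested here and 1023 and 948 called in the same direction.

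**Figure D1:**
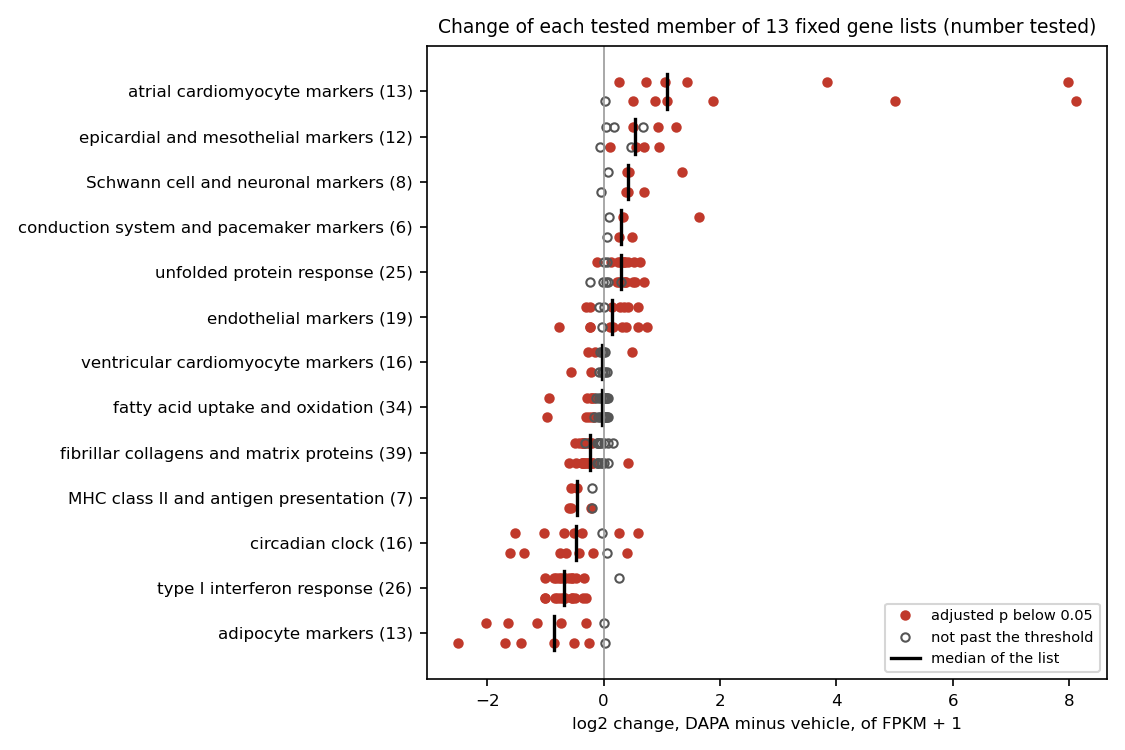
Each point is 1 tested gene, placed by its log2 change in FPKM + 1 (DAPA minus vehicle, horizontal axis), for 13 gene lists fixed beforehand (vertical axis, number tested in brackets). Filled points passed an adjusted p of 0.05, open points did not, and bars mark list medians, from 1.10 for atrial markers to -0.85 for adipocyte markers.

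Transcripts of the atrial myocardium were higher in each DAPA library, and several were nearly missing from the vehicle libraries. Sln (NCBI Gene 66402), encoding sarcolipin, the inhibitor of the calcium pump in atrial muscle, measured 0.278 ± 0.41 in vehicle and 312 ± 19.1 in DAPA libraries. Those values rest on 15 and 16913 reads, a ratio of 1130 with a 95% counting interval of 684 to 2020. Vehicle library 1 held 12 of the 15 reads, and without it the ratio was 4230 (1450 to 20500). Myl7 (17898), the atrial regulatory myosin light chain, rose from 1.34 ± 1.1 to 603 ± 27.8 (log2 change 8.12, SE 0.22, adjusted p = 4.7e-11), a ratio of means of 450.0 that was 745 without vehicle library 1. The essential light chain of atrial myosin, Myl4 (17896), rose from 0.413 ± 0.0566 to 44.5 ± 2.04, 108-fold (adjusted p = 1.4e-15). Mybphl, a myosin-binding protein of the atrium, rose from 0.0891 ± 0.0526 to 58.2 ± 4.08 on 12 and 7734 reads. Bmp10, a growth factor made by atrial muscle, had 1 read in the 4 vehicle libraries and 1852 in the DAPA libraries, a ratio of 1850 with an interval of 332 to 73200. That read lay in vehicle library 1, and without it the lower bound was 376. Stard10, a lipid transfer protein, started higher, at 11.8 ± 0.748, and rose 3.91-fold to 46.2 ± 2.18. Of the 13 tested atrial markers, 12 rose and none fell (12 and 0 adjusted over the list alone), with a median log2 change of 1.10 (camera adjusted p = 1.1e-24, and 0.0042 with an estimated correlation). Nr2f2, named after its values were seen, was the member that did not pass (0.03, adjusted p = 0.83).

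The other largest rises were of Hamp (hepcidin, 0.309 ± 0.21 to 12.6 ± 1.55), Tmem163 (0.0461 ± 0.0282 to 7.40 ± 0.66), Mlana (0.610 ± 0.357 to 10.3 ± 0.851) and Sost (sclerostin, 0.337 ± 0.0627 to 4.00 ± 0.576). A pair of related kinase genes rose with them, Sbk3 from 0.563 ± 0.117 to 8.42 ± 0.465 and Sbk2 from 0.879 ± 0.125 to 6.82 ± 0.595.

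Markers of the epicardium, the conduction system and nerves rose in the same libraries. Among 12 epicardial and mesothelial markers 7 rose and none fell (10 and 0 adjusted over the list alone), among them mesothelin (Msln, 5.23 ± 1.28 to 13.7 ± 2.59), Gpm6a (2.19-fold) and keratin 8 (Krt8, 3.31-fold). Of 8 Schwann cell and neuronal markers 6 rose and none fell (6 and 0 adjusted over the list alone), among them Dbh, which makes noradrenaline in sympathetic nerves and rose 1.53-fold. Among 6 conduction system markers 4 rose and none fell (4 and 0 adjusted over the list alone), including the calcium channel subunit Cacna2d2 (0.228 ± 0.0721 to 2.84 ± 0.213), Cntn2 (1.75-fold) and the connexin Gja5 (1.23-fold). The list calls (camera adjusted p = 2.9e-05, 3.8e-04 and 8.7e-04) were lost with an estimated correlation, where the adjusted p was 0.24, 0.082 and 0.17. Of 16 ventricular cardiomyocyte markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone), with a median of -0.03 (camera adjusted p = 0.035; adjusted p = 0.69 with an estimated correlation).

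Interferon-stimulated genes were lower in the DAPA libraries. Oasl2 (23962), an antiviral protein of the oligoadenylate synthetase family, fell from 17.1 ± 0.592 to 7.98 ± 0.435, 2.15-fold (log2 change -1.01, SE 0.047, adjusted p = 1.0e-08). Ifit3, an inhibitor of viral translation and replication, fell from 23.9 ± 0.901 to 13.9 ± 0.75. The transcription factors of the response fell too, Irf7 from 42.4 ± 2.03 to 26.2 ± 1.23 and Irf9 from 23.8 ± 0.682 to 14.7 ± 0.806. Of 26 tested genes of the type I interferon response, 25 fell and none rose (25 and 0 adjusted over the list alone), with a median log2 change of -0.67 (camera adjusted p = 5.1e-28, and 0.0015 with an estimated correlation). The chemokine Cxcl10, named after its values were seen, was the exception, at 0.27 (adjusted p = 0.21). In the same libraries the atrial markers differed by a median of 1.10 and the adipocyte markers by -0.85.

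Antigen presentation and B lineage transcripts were also lower in these libraries, which differ in atrial markers by a median of 1.10. Of 7 genes for MHC class II and its partners 5 fell and none rose (7 and 0 adjusted over the list alone). H2-Aa fell from 138 ± 8.4 to 93.1 ± 3.42, H2-Eb1 by 1.51-fold, H2-Ab1 by 1.49-fold and Cd74, the invariant chain, by 1.37-fold. Jchain, which joins the subunits of secreted IgA and IgM, fell from 8.45 ± 1.72 to 1.57 ± 0.48 (log2 change -1.88, SE 0.14, adjusted p = 8.4e-07). Of 5 tested B and plasma cell markers 3 fell and none rose (4 and 0 adjusted over the list alone). The calls of both lists (camera adjusted p = 2.8e-07 and 0.0018) were lost with an estimated correlation (adjusted p = 0.16 and 0.17). Macrophage and monocyte markers went both ways, with 6 of 23 higher and 5 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.81). Plac8 fell 3.35-fold and Mpeg1, a pore-forming protein of phagocytes, 1.3-fold, while Csf1r, the receptor that keeps macrophages alive, rose 1.16-fold.

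**Figure D2:**
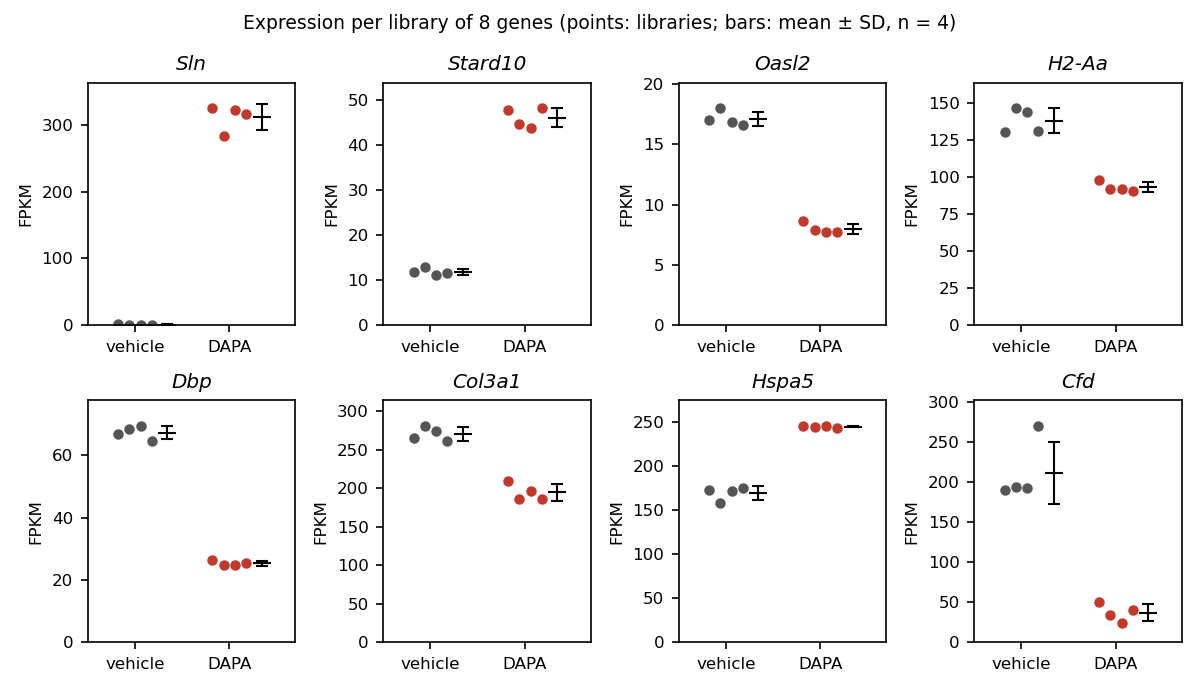
FPKM (vertical axis, starting at 0) of 8 genes in the 4 vehicle and 4 DAPA libraries (horizontal axis); points are libraries and bars are mean ± SD. The groups do not overlap in any panel: Sln, Stard10 and Hspa5 are higher with DAPA, and Oasl2, H2-Aa, Dbp, Col3a1 and Cfd are lower, with 1 vehicle library at 270.2 FPKM of Cfd.

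Output genes of the circadian clock were lower with DAPA. Dbp (13170), a transcription factor driven directly by the clock, fell from 67.2 ± 2.1 to 25.3 ± 0.785 (log2 change -1.37, SE 0.036, adjusted p = 3.7e-11). The repressors Nr1d1 and Per1 fell from 23.7 ± 1.34 to 7.09 ± 0.404 and from 12.3 ± 0.562 to 3.62 ± 0.253, and Nr1d2 fell 1.63-fold. Of 16 tested clock genes 11 fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 3.9e-08, and 0.018 with an estimated correlation). Among the 3 that rose were Nfil3 (0.59) and Clock (0.26), named after their values were seen. The labels give no time of collection, and atrial markers were higher in the same libraries by a median of 1.10.

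Collagen and matrix genes were modestly lower. Col1a1 and Col3a1, the chains of the main fibrillar collagens, fell from 109.6 ± 8.41 to 84.3 ± 2.2 and from 271 ± 8.77 to 195 ± 10.8 (adjusted p = 1.1e-04 and 2.3e-06). Postn (periostin), made by activated fibroblasts, fell from 381 ± 5.56 to 314 ± 12.5. The largest change in the list was that of Thbs4 (1.52-fold lower), followed by Cilp (1.42-fold lower), while Ltbp2, which binds to elastic fibres, was 1.35-fold lower. Of 39 matrix proteins 22 fell and 1 rose (24 and 2 adjusted over the list alone), with a median of -0.24, and the riser, named after its values were seen, was elastin (Eln, 0.41). The list call (camera adjusted p = 2.6e-12) was lost with an estimated correlation (adjusted p = 0.24). Among 24 enzymes that remodel matrix, 10 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.24 with an estimated correlation). Fibroblast markers, 7 of them shared with the matrix list, moved in the same libraries, with 7 of 20 lower and 2 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.038; adjusted p = 0.66 with an estimated correlation). So did matrifibrocyte markers, 5 of them shared, with 5 of 13 lower and 2 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.031; adjusted p = 0.56 with an estimated correlation). In these libraries the ventricular transcript Myl2, named after its values were seen, fell from 3147 ± 82.5 to 2835 ± 124 (log2 change -0.15) while the atrial markers rose by a median of 1.10.

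The natriuretic peptides were higher. Nppa, which atrial muscle makes in large amounts and which is also in the atrial list, rose from 8481 ± 447 to 12070.1 ± 305 (1.42-fold, adjusted p = 6.2e-07). Nppb rose from 976 ± 25.4 to 1240.5 ± 45.6 (1.27-fold, adjusted p = 5.4e-06). Their clearance receptor Npr3 rose 3.35-fold, and the signalling receptor Npr1 1.25-fold. Of 13 genes of the renin-angiotensin and natriuretic peptide system 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0045; adjusted p = 0.1 with an estimated correlation), in libraries whose atrial markers were higher by a median of 1.10. The cardiac myosin heavy chains did not pass the test, with Myh6 at 2396 ± 153 and 2361 ± 73.7 (adjusted p = 0.8) and Myh7, the fetal form, at 265 ± 21.6 and 290.1 ± 13.2 (adjusted p = 0.099). Without vehicle library 1, Myh7 passed (adjusted p = 0.0352), as it did in limma voom on the recovered reads (0.00232), an alternative chosen after seeing the data. Over all 18 alternatives its adjusted p ranged from 0.00232 to 0.223.

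Most genes of the unfolded protein response were higher with DAPA. Manf, secreted upon stress of the endoplasmic reticulum, rose from 59.0 ± 1.6 to 91.8 ± 3.87 (log2 change 0.63, SE 0.036, adjusted p = 7.7e-08). Hspa5 (14828), the main chaperone of that compartment (BiP), rose from 169.7 ± 7.53 to 245 ± 0.817, Hsp90b1 by 1.31-fold and the disulfide isomerase Pdia6 by 1.35-fold. Of 25 genes of the unfolded protein response 17 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 3.8e-11, and 0.044 with an estimated correlation). Herpud1, named after its values were seen, was the member that fell (-0.12). The same libraries were higher in atrial markers, by a median of 1.10.

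Adipocyte transcripts were much lower in the DAPA libraries. Cfd (11537), the adipokine adipsin, fell from 211 ± 39.2 to 37.3 ± 10.8 (log2 change -2.50, SE 0.17, adjusted p = 3.6e-07). Adipoq (adiponectin) fell from 12.7 ± 2.35 to 3.46 ± 1.25, and Cidec, which enlarges lipid droplets, from 8.63 ± 0.318 to 1.41 ± 0.523. Car3, a carbonic anhydrase abundant in fat, fell 3.3-fold and Thrsp, a regulator of lipid synthesis, 1.67-fold, in libraries whose atrial markers were higher by a median of 1.10. Of 13 adipocyte markers 11 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 3.9e-12; adjusted p = 0.093 with an estimated correlation). That median was -1.74 with a pseudocount of 0.1, -1.75 with 0.01, and -1.75 with limma voom on the recovered reads, an alternative chosen after seeing the data, where the atrial median was 1.34. The remaining largest falls were of Cyp2e1 (22.5 ± 2.18 to 3.17 ± 1.07), Pck1, an enzyme of gluconeogenesis and glyceroneogenesis (2.81 ± 0.27 to 0.245 ± 0.161), Nnat (2.78 ± 0.777 to 0.293 ± 0.0739), haptoglobin (Hp, 27.7 ± 4.45 to 9.49 ± 1.97) and the metallothionein Mt2 (147 ± 2.88 to 53.7 ± 6.28).

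Fuel genes changed in part. Pdk4, which holds back glucose oxidation, fell from 65.6 ± 3.89 to 33.0 ± 1.17 (adjusted p = 8.2e-09) and the mitochondrial carrier Ucp3 from 11.3 ± 0.41 to 5.37 ± 0.254. The fatty acid binding proteins Fabp4, also an adipocyte marker, and Fabp3, also a ventricular marker, fell 1.23-fold and 1.17-fold. Of 34 genes for fatty acid uptake and oxidation 10 fell and none rose (12 and 0 adjusted over the list alone), in libraries whose adipocyte markers differed by a median of -0.85 (camera adjusted p = 0.0021; adjusted p = 0.44 with an estimated correlation). Of 18 genes of the TCA cycle 4 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.72 with an estimated correlation). Of 62 nuclear genes for oxidative phosphorylation 5 rose and 10 fell (6 and 14 adjusted over the list alone; camera adjusted p = 0.035; adjusted p = 0.72 with an estimated correlation). The median changes of the fatty acid, TCA cycle and oxidative phosphorylation lists were small, at -0.02, 0.04 and -0.03. In ketone body metabolism 2 of 8 genes rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.87). Bdh1, which oxidises 3-hydroxybutyrate, was the one that fell, from 64.5 ± 1.28 to 44.8 ± 1.35 (log2 change -0.52, adjusted p = 1.8e-07). Oxct1, the next enzyme of ketone use, measured 300.4 ± 9.27 and 294 ± 9.51 (adjusted p = 0.58).

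Endothelial genes moved both ways, with 11 of 19 markers higher and 5 lower (11 and 6 adjusted over the list alone). The tight junction gene Cldn5 rose from 36.4 ± 1.59 to 62.0 ± 3.28, von Willebrand factor (Vwf) 1.53-fold and Plvap, of the diaphragms of fenestrae and caveolae, 1.52-fold, whereas Rgcc fell from 161 ± 6.23 to 94.2 ± 2.76. The list call (camera adjusted p = 0.034) was lost with an estimated correlation (adjusted p = 0.44) and without vehicle library 2 (adjusted p = 0.071, in a range of 0.00683 to 0.444 over 19 alternatives). Atrial markers were higher in the same libraries by a median of 1.10.

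The drug's own target was close to the limit of detection. Slc5a2, encoding SGLT2, had 26 reads over the 4 vehicle and 12 over the 4 DAPA libraries (0.110 ± 0.0288 and 0.0516 ± 0.0602). DAPA library 3 held 8 of the 12, and without it the ratio of mean FPKM went from 0.469 to 0.206. Slc5a1, encoding SGLT1, had 53 and 43 reads. Both lay below the expression filter, as did Il1b (60 and 124 reads) and Nlrp3 (122 and 102 reads), so none of these was tested with the filter in place. Without the filter, Il1b was higher with DAPA (0.422 ± 0.117 and 0.879 ± 0.242, adjusted p = 0.034) and the others did not pass (Slc5a2 0.27, Slc5a1 0.73, Nlrp3 0.74). Of 14 genes for sodium and proton transport 1 rose and 4 fell (1 and 4 adjusted over the list alone), and of 13 inflammasome genes none rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.42 and 0.096).

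Averaged over markers, 11 of the 25 cell type and quality lists separated the groups completely, at the smallest p that the exact permutation test allows (0.0286). None passed after adjustment over the 25 lists (adjusted p = 0.065 for those 11), as none can unless most of the 25 reach that smallest p. The mean log2 level of atrial markers was 3.06 ± 0.0726 in vehicle and 5.42 ± 0.0429 in DAPA libraries, and that of adipocyte markers 4.22 ± 0.115 and 3.39 ± 0.118. Higher too were the epicardial, conduction, Schwann cell, skeletal muscle, endothelial and lymphatic endothelial means, by 0.08 to 0.46. The means of B and plasma cells (-0.45), neutrophils (-0.08) and erythrocytes (-0.13) were lower. Of the 5 neutrophil markers that passed the filter, however, 2 rose and none fell (2 and 3 adjusted over the list alone), with a camera adjusted p of 0.69. Of 9 tested erythrocyte markers none rose and 1 fell (1 and 1 adjusted over the list alone). Of 10 skeletal muscle markers 3 rose and 2 fell (4 and 2), and of 7 lymphatic endothelial markers 2 rose and none fell (2 and 0). These lists did not pass either (camera adjusted p = 0.42, 0.33 and 0.25). Fibroblast markers averaged 6.49 and 6.43 (exact permutation p = 0.0857).

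Over all 55 lists tested, 27 passed with the preset correlation, 11 higher and 16 lower, and 4 passed with an estimated one: the type I interferon response, atrial markers, the circadian clock and the unfolded protein response. Among signs of RNA quality, the 38 cytosolic ribosomal proteins were lower, with a median of -0.10, 5 lower and none higher (1 and 0 adjusted over the list alone; camera adjusted p = 1.8e-06; adjusted p = 0.61 with an estimated correlation). Their mean log2 level was 9.31 in vehicle library 2 and 9.08 to 9.17 in the other vehicle libraries, against 9.06 to 9.11 in DAPA libraries. Of 23 chemokines and cytokines 2 rose and 6 fell, of 26 antioxidant genes 1 and 7, and of 22 lipid droplet genes 3 and 10 (3 and 10, 1 and 7, and 3 and 10 adjusted over the list alone). These lists passed as lower (camera adjusted p = 0.018, 0.035 and 0.049), and were lost with an estimated correlation (adjusted p = 0.31, 0.5 and 0.24). Their medians were -0.10, -0.02 and -0.008, and the lipid droplet list shares 4 genes with the adipocyte markers. The 28 lists that did not pass with the preset correlation included sarcomere genes, calcium handling, glycolysis, TGF-beta signalling, myofibroblast genes, complement, hypoxia and apoptosis.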

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

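In each group of 4 libraries, every named gene, every mean marker level, the reads per library and the genes above 0 were searched for a library far from the other 3, measured as its gap to the nearest divided by the range of the group. Of 254 groups searched, 12 stood out, about as many as chance gives (1 in 20, or 12.7).

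Vehicle library 4 was high in fat transcripts. It held 270.2 FPKM of Cfd against 190.1 to 193.5 in the other 3 (gap over range 0.957), 88.6 of Car3 against 63.6 to 64.9 (0.947), 16.2 of Adipoq against 11.24 to 11.98 (0.848), and a mean adipocyte marker level of 4.39 on the log2 scale against 4.14 to 4.18 (0.852).

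Endothelial markers were low in library 2 of both groups. Their mean log2 level was 6.37 against 6.42 to 6.43 in vehicle libraries (0.981) and 6.50 against 6.53 to 6.54 in DAPA libraries (0.864).

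The single read of Bmp10 in the vehicle group lay in library 1, at 0.029 FPKM against 0 in the others (gap over range 1.0). Zfp36 was also high there, at 25.5 FPKM against 22.2 to 22.6 (0.861). In the DAPA group, library 1 was high in H2-Aa, at 98.2 against 90.8 to 91.7 FPKM (0.878), and low in Egr1, at 13.8 against 14.4 to 14.5 (0.894). Library 2 was low in Sbk3, at 7.73 against 8.56 to 8.72 (0.841), and library 4 low in H2-Eb1, at 49.4 against 55.5 to 56.5 (0.861).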

How the results depend on the processing

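The count of 2112 genes stayed within 1.5 times of its value under both other scalings, no filter, the stricter filter and both other pseudocounts. It did so too with sample quality weights, robust moderation, an adjusted p of 0.1 (2857) and voom on the recovered reads (2582). Of the 2112 genes, 1998 were among those called by voom and all 2112 went in the same direction. Leaving out the atrial, conduction, epicardial, Schwann cell and adipocyte lists gave 2073. Those lists hold only 13, 6, 12, 8 and 13 tested genes, too few to move the count that far, so this does not test a difference in tissue. Voom and this last count were chosen after seeing the data. With 1 library left out the count ranged from 1693 to 1892. It moved to 3600 at an unadjusted p of 0.05 and to 81 against a fold of 1.5 (limma treat), as those thresholds are looser and stricter by construction. The share of higher genes was 52.4% as deposited, 47.7% with median-of-ratios and 49.4% with upper-quartile scaling. Lists called stood at 33 with fry, which asks a different question, and fell from 27 to 4 when the correlation was estimated. Correlated members do not account for the whole of that fall. The estimate for the interferon list was 0.01, the preset itself, yet its unadjusted camera p went from 9.3e-30 to 2.8e-05. Heat shock proteins (-0.0395) and the renin-angiotensin list (-0.00899) lost their calls at estimates below the preset, whereas the matrix list had 0.385. With an estimated correlation, camera also takes its degrees of freedom from the 8 libraries instead of the genes. That alone raises the p-values, so a call lost in that setting is by itself no sign of correlated members. The share of each part in the fall was not tested. With 1 library left out, 22 to 29 lists were called. No list of mean marker levels passed after adjustment, nor with the median over markers or with any 1 library left out, the alternatives run for it. With all libraries, 11 of the 25 lists reached the smallest permutation p of 0.0286, which adjusts to 0.065. No list can pass at that p unless most of the 25 reach it, so the failure to pass is no sign of equal levels.

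Of the 100 genes that the naming rule takes, under all settings together, 1715 of 1731 values kept their direction and their side of the threshold, 11 were weaker, 5 stronger and none reversed, in 7 genes. The log2 changes of 20 called genes moved by over 1.5 times with a smaller pseudocount or voom, and the medians of 8 called lists did so under those settings, with no filter or with 1 library left out. Among these, besides Myh7 and Il1b, the call of Hcn4 was lost without DAPA library 2 or 3, that of Acat1 without DAPA library 4, that of Cd79b with no filter, and Cd79a passed without vehicle library 2. With the replicate number as a block, 1764 genes were called, 906 higher and 858 lower, and of the named results Cd79a alone changed sides. Same-numbered libraries did not deviate together (correlations of -0.0551 to 0.0138 over 4 pairs), so the numbers are not taken to pair them.

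The planned count models were not run, since the table holds FPKM, nor was the setting without mitochondrially encoded genes, since none is in the table. Total-count scaling is already in FPKM, so it gave no further value. Depth limits the genes below the filter: Slc5a2, Slc5a1, Il1b and Nlrp3 rest on 12 to 124 reads per group.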

Other observations

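Further lists fixed beforehand moved as well, in libraries whose atrial and endothelial markers were higher by medians of 1.10 and 0.15. Of 18 heat shock proteins 10 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.089 with an estimated correlation), with the cochaperone Dnaja1 up 1.26-fold, Hsp90aa1 1.2-fold and Hsp90ab1 1.13-fold, and the small heat shock protein Hspb6 down 1.17-fold. Of 23 immediate early genes 10 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.24 with an estimated correlation). Klf4 rose from 11.8 ± 0.533 to 17.0 ± 0.454 FPKM and Egr1 from 10.1 ± 0.445 to 14.3 ± 0.332, while Zfp36, which promotes the decay of cytokine transcripts, fell 1.44-fold. Among 24 angiogenic factors and receptors, 3 of them also endothelial markers, 8 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0087; adjusted p = 0.38 with an estimated correlation). Angpt1, the ligand that steadies vessels, rose from 6.30 ± 0.625 to 14.0 ± 0.337, its receptor Tek 1.35-fold and the apelin receptor Aplnr 1.35-fold.

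Of the tests below, those on atrial tissue, scaling, dilution, time of day and the splits of the libraries were chosen after the values they measure were seen. The one on glucocorticoid-responsive genes was written down before, although the idea came from other such genes seen to fall. Those were left out of its list, as was Dusp1, a glucocorticoid-responsive gene already seen to rise (log2 change 0.18, adjusted p = 0.0084).

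Chance was set against the comparison by refitting all 35 splits of the 8 libraries into 4 and 4. The labelled split alone gave as many genes (1 of 35), with 2112 against at most 1 in any other, and as many genes past a fold of 1.5 (1 of 35), with 81 against 0. It also gave the most lists (1 of 35), 27 against up to 24. A share of 1 of 35 is the lowest that these splits allow, so they speak against a chance split at that level and no further. Every other split leaves the group difference inside its own groups, which widens their spread and by itself lowers the gene calls there. As the libraries of a group may not be separate animals, chance differences between animals are not excluded. The 16 splits that exchange 1 library between the groups, and so keep part of the group difference, called 12 to 24 lists. The 18 evenly mixed splits, which keep none of it, called 0 to 12, so some list calls at the preset correlation can arise without a group difference.

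The rise of atrial genes may come from atrial tissue in the DAPA samples that the vehicle samples lacked. The rise of 12 of the 13 tested atrial markers, of which 9 had a mean of at least 1 FPKM in the vehicle libraries and 7 stand in another fixed list, is the observation itself and would follow from an effect of DAPA on these genes too. Added atrial tissue should also lower the ventricular light chains, of which Myl2 fell by 0.15 (adjusted p = 0.007) and Myl3, named after its values were seen, changed by -0.03 (adjusted p = 0.5). A scaling factor shared by all genes is argued against, because the median change of all tested genes as deposited, before any other scaling, was 0.0085 against 1.10 for the atrial markers. The labels name heart and no chamber, so atrial tissue from a difference in dissection and an effect of DAPA cannot be told apart.

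Lower interferon and matrix genes could follow from the same atrial tissue diluting ventricle, in which case they should fall no further than ventricular transcripts. The interferon list, with a median of -0.67 and an upper bootstrap bound of -0.549 (95%, 10000 resamples), fell further than Myl2, which fell by 0.15 (SE 0.034). Of the 16 ventricular markers, with a median of -0.03, 15 lay at -0.269 or higher, well above that bound, and Tcap alone, named after its values were seen, reached it at -0.556. Atrial tissue should dilute Myl2 in full, and the whole interval (-0.749 to -0.549) lay below Myl2 less 2 standard errors (-0.218). These values argue against dilution as the whole cause of the lower interferon list. They do not exclude it, as Myl2 is a single gene, Tcap reached the bound and atrial muscle also makes most of the other markers. The bound of the matrix list, -0.102 around a median of -0.24, reaches the fall of Myl2. Dilution thus stays open for the matrix list as a whole, as does an untested effect of DAPA on either list. Of the matrix genes fixed for naming beforehand, Col1a1 (-0.372), Col3a1 (-0.473) and Postn (-0.279) fell further than Myl2. Of all 39 tested members 22 fell, 1 rose and 16 did not pass.

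Lower clock output genes may reflect collection at another time of day. Clock genes of the opposite phase should then rise, and all 5 of them, each also in the fixed clock list, had a positive change (collection at another time of day): Arntl from 0.198 to 0.716 FPKM and Npas2 from 0.378 to 0.668, both below the filter (adjusted p without it 6.1e-05 and 0.014), Clock from 4.62 to 5.74, Nfil3 from 3.32 to 5.53 and Cry1 from 7.19 to 7.56, the last not past the threshold (adjusted p = 0.479). Lower glucocorticoid action was tested with 15 responsive genes chosen before their own values were seen, 6 of them in fixed lists whose list results were known. Of the 14 that passed the filter 13 fell, such as Sgk1 (40.4 to 28.3 FPKM), and 1 (Lcn2) rose, with a median of -0.36, and 0 of 10000 random lists matched on mean FPKM were as low (lowest -0.14). Random lists are drawn without regard to shared regulation, so genes regulated together by something else could fall as far. The comparison with them thus does not single out glucocorticoid action. Corticosterone itself follows the time of day, so both explanations stay open, as does an untested effect of DAPA.

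Of 5 lists examined for their spread between libraries of a group, adipocyte markers stood out in both groups against other genes of like abundance. Their median chi-square per degree of freedom was 10.9 in vehicle libraries and 8.94 in DAPA libraries, above all of 10000 lists matched on reads in the first group and 99.94% of them in the second, where those lists had medians of 3.89 and 3.39. Endothelial markers in DAPA libraries (8.58 against 4.66) lay above 99.36% of their matched lists but in vehicle libraries (6.15 against 6.33) above 47.46%. Interferon genes lay above 97.32% in vehicle (4.75 against 3.25) and 74.66% in DAPA libraries (3.21 against 2.79), while atrial and erythrocyte markers lay above 50.37% to 91.02%. Between libraries of a group, genes with 500 to 2000 reads had a median coefficient of variation of 5.59% in vehicle and 5.36% in DAPA libraries, where counting alone gives 3.21% and 3.2%.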
